A study of Mus musculus with 2 samples.

How the data were processed

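Peritoneal macrophages were taken from mice labelled sufficient or deficient in ECM1, extracellular matrix protein 1, after 3 days of elicitation with an agent the labels call ThG. The cells were not activated further. The labels give 1 ECM1-sufficient and 1 ECM1-deficient sample, each with 1 RNA sequencing library. Per the labels' protocol, polyadenylated RNA was selected with oligo(dT) beads and the libraries kept strand information through dUTP in the second cDNA strand.

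Expression was deposited as FPKM, fragments normalised to transcript length and to the number of mapped fragments, which the authors computed per gene. The submitters' processing notes name HISAT2, without a version, StringTie 1.2.3 and the build mm9. The coordinates in the table were compared with GENCODE M21 on GRCm38. Of the 10403 gene identifiers, 10384 were in that annotation, all 10384 overlapped the gene of the same identifier, and 8060 had the identical start and end, so positions below are given as GRCm38. The table held 10403 genes with values under 10402 symbols, all typed as protein-coding. The lower bound of the higher FPKM of a gene was 0.500, so genes below about 0.5 FPKM in both libraries had been left out. The values of 1 line of the table and of some single genes are not reported here.

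The columns headed FPKM with a suffix held log2(FPKM + 1) in the deposited table, and the authors' log2 fold change was the ECM1-sufficient value minus the ECM1-deficient value. The largest gap from these relations was 7.67e-14. The authors' fold ratio was the linear form of that difference. Every p-value and q-value in the deposited table was 1. The authors' gene ontology table listed biological process terms with a fold ratio of enrichment, a p-value and a false discovery rate, per the file headers. The authors' table of 1 KEGG pathway, arginine and proline metabolism, held a rank metric score and a running enrichment score of gene set enrichment analysis. That metric equalled the difference of the FPKM values divided by 0.2 times their sum. The number of reads per library is unknown, because low FPKM values showed no steps of whole reads, and no counting interval is given.

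From the linear FPKM values, the difference of each gene was computed as log2(FPKM + 1) in the ECM1-deficient library minus that in the ECM1-sufficient library. The scale understates the differences of weakly expressed genes. Rows of the same symbol were summed, which concerned 1 symbol, and 9032 genes at 1 FPKM or more in at least one library were kept. A gene was counted as higher or lower when the difference reached 1 in size, which is 2-fold in FPKM + 1. Folds printed for single genes are ratios of FPKM without the added 1. Genes of low FPKM can therefore be past 2-fold by that ratio and still be counted as within 2-fold. With 1 library per genotype there was no test, and no difference has a replicate check. Values relative to the median gene used the median ratio of the 7329 genes at 1 FPKM or more in both libraries. Before 1 was added, ECM1-deficient FPKM were divided, and ECM1-sufficient FPKM multiplied, by the square root of that ratio. Below this is called division by the median ratio. FPKM were also rescaled to the same sum in both libraries.

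The lists of genes were fixed before the data were examined, 33 in number, and the authors' KEGG set was treated as a further list. For lists with at least 5 measured members, the median difference was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes these libraries and is not a test. The named genes followed a rule fixed before the data were examined. Ecm1, Arg1 and Nos2 were always included, with the 12 highest and 12 lowest differences, leaving out 295 predicted models and clone names. From each list up to 4 members past 2-fold were added, or 2 by expression where none was past it, with up to 6 genes of the KEGG set and the 10 most expressed genes. Further members are given as examples of their list. A ranking of genes with 3 or more exons and 5 FPKM or more in both libraries was added after the values were seen. Exon numbers and transcript lengths came from GENCODE M21.

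Alternatives were pseudocounts of 0.1 and 5, no FPKM minimum, a minimum of 5 FPKM, both rescalings, thresholds of 1.5-fold and 4-fold, and the highest row per symbol. Gene models with 3 or more exons, random lists also matched on transcript length, and lists without members at under 5% of their level in the other library were added after the data were seen. The calculation was tested on simulated data for the same 9032 genes with a common shift of 0.79. The recovered shift was 0.77, and 99.0% of 200 genes changed 8-fold were past 2-fold after scaling, against 0.0906% of the unchanged genes. The simulated noise was normal with an SD of 0.35, set from the median absolute deviation of the real differences. It lacks their wide tails, with an SD of 2.501 over genes with 1 exon. The 0.0906% is therefore not an error rate of these libraries. Of 100 simulated lists with no change, 5 lay outside the middle 95% of random lists, and all 40 lists of 15 genes shifted by -0.60 lay below it. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.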

Results

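RNA of elicited, non-activated peritoneal macrophages was measured in 1 ECM1-sufficient and 1 ECM1-deficient library. The comparison asks which genes differ in these macrophages when ECM1, a secreted glycoprotein of the extracellular matrix, is deficient. There were no replicates, so each value below is that of a single library. The FPKM of the listed genes summed to 137135 in the ECM1-sufficient library and 187612 in the ECM1-deficient library, 1.37 times as much. Sequencing depth is unknown.

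Ecm1 itself lies on chromosome 3 from 95734147 to 95739569 and has 11 exons. It was at 5.63 FPKM in the ECM1-sufficient library and 1.02 FPKM in the ECM1-deficient library, 5.51-fold lower. Its difference was -1.71, and -2.24 relative to the median gene. The direction matches the genotype labels, and 18.2% of the FPKM remained. Of 15 measured neighbours of Ecm1 on its chromosome, 1 was higher, 1 lower and 13 within 2-fold, with a median of 0.73 at percentile 84.7 of random lists, and relative to the median gene 0 were higher and 1 lower. Ctsk, which encodes the collagen-degrading protease cathepsin K, was the higher one, and the mitochondrial ribosomal protein gene Mrps21 was the lower one, at 261 against 62.4 FPKM.

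Most genes had more FPKM in the ECM1-deficient library. Of 9032 genes, 8172 were higher and 860 lower there, and the median difference was 0.61. Differences from the 5th to the 95th percentile ran from -0.36 to 1.28. At least 2-fold, 1337 genes were higher and 196 lower, so that 87.2% of these genes were higher. The median ratio of genes measured in both libraries was 1.73-fold, or 0.79 on the log2 scale. Relative to that shift, 221 genes were higher and 431 lower, a share of 33.9% higher, and with FPKM rescaled to equal sums 833 were higher and 387 lower, a share of 68.3%. Counts for the gene lists are therefore also given relative to the median gene.

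**Figure D1:**
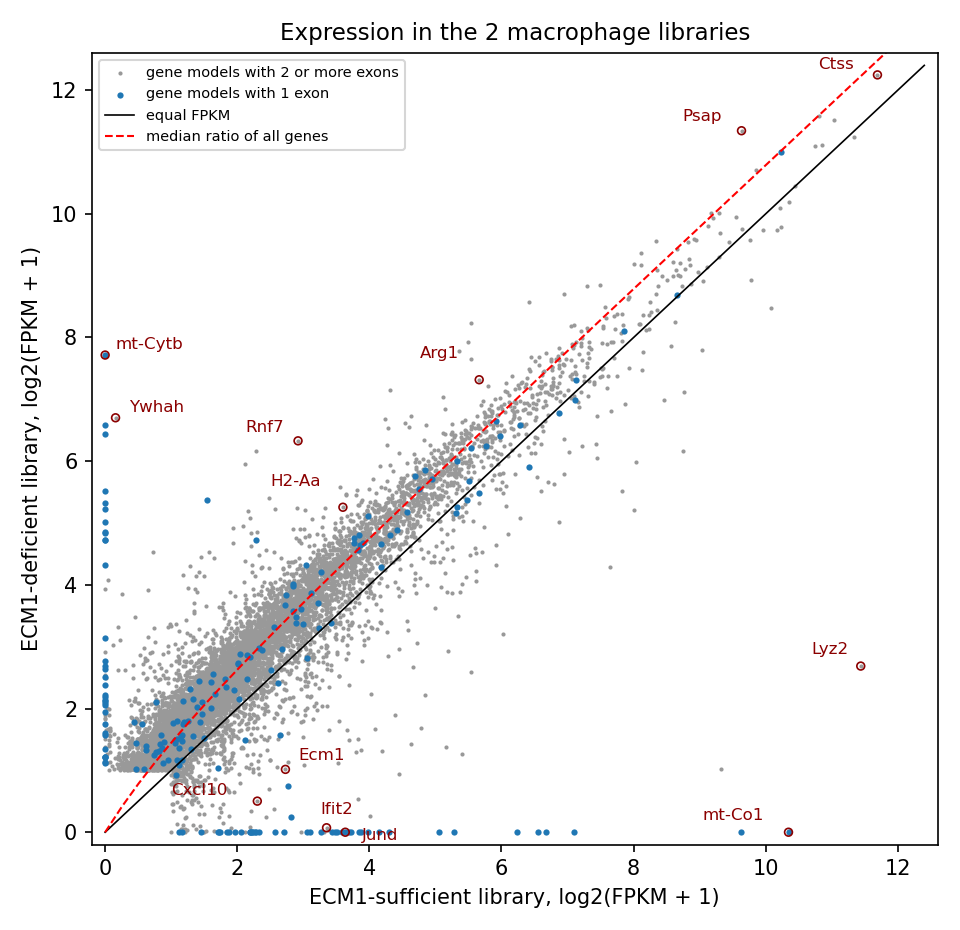
Each point is 1 gene, with log2(FPKM + 1) in the ECM1-sufficient library on the horizontal axis and in the ECM1-deficient library on the vertical axis. Most of the 9032 genes lie above the line of equal FPKM and around the dashed line of the median ratio, and several genes with 1 exon lie on an axis, listed at 0 in either library.

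The 10 genes with the highest FPKM summed over both libraries were Ctss, Ctsd and Psap, which encode lysosomal proteins, Lgals3, Cd63, Fth1, Tmsb4x, Tyrobp, mt-Nd6 and Lyz2. Ctss, the protease cathepsin S, was at 3305 and 4856 FPKM, and Ctsd at 1794 and 3064 FPKM. Tyrobp, a signalling adaptor of myeloid receptors, was nearly level at 1386 and 1399 FPKM, and Tmsb4x, an actin-binding peptide, was at 2583 and 2427 FPKM. Fth1 was at 2090 and 2914 FPKM, Lgals3 at 1852 and 2209, Cd63 at 1720 and 2197, and mt-Nd6 at 1199 and 2040. Psap, the precursor of saposins, was 3.27-fold higher in the ECM1-deficient library, 0.92 relative to the median gene. Lyz2, which encodes the lysozyme of macrophages, was at 2774 FPKM in the ECM1-sufficient library and 5.44 FPKM in the ECM1-deficient library, 510-fold lower. Of 20 macrophage core genes, 7 were higher, 1 was lower and 12 within 2-fold. Fcgr1, a high-affinity immunoglobulin receptor, was 4.72-fold higher, Spi1, the macrophage transcription factor PU.1, 4.28-fold and Sirpa 2.33-fold higher. The list's median was 0.81, at percentile 95.02, and relative to the median gene 2 were higher and 1 lower.

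Arg1 was higher in the ECM1-deficient library, and the list of arginine metabolism lay within the middle 95% of random lists. Arginase 1, which splits arginine to ornithine and urea, lies on chromosome 10 from 24915208 to 24927470. Its gene Arg1 was at 49.6 FPKM in the ECM1-sufficient library and 158 FPKM in the ECM1-deficient library, 3.19-fold higher. That difference of 1.65 was exceeded by 198 genes and was 0.88 relative to the median gene. Of 25 arginine, proline and polyamine genes, 9 were higher, 0 lower and 16 within 2-fold, with a median of 0.81 at percentile 95.3. Glul, glutamine synthetase, was 7.40-fold higher, P4ha1, a subunit of collagen prolyl hydroxylase, 3.08-fold and the transaminase Got1 2.68-fold higher. Slc7a2, an arginine transporter, was at 2.57 and 1.06 FPKM. Relative to the median gene, 1 gene of this list was higher, Glul, and 1 lower, Slc7a2.

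The authors' deposited table of the KEGG arginine and proline set named 34 genes, of which 22 belonged to its core. A negative metric, which is the ECM1-deficient direction, was held by 32 of the 34. Of all 9032 genes, 90.5% were higher in the ECM1-deficient library. The set's lowest running enrichment score was -0.375. Of 29 members measured here, 11 were higher, 0 lower and 18 within 2-fold, with a median of 0.85 at percentile 99.2, or 96.9, inside the middle 95%, with random lists also matched on transcript length. Its median was 0.21 relative to the median gene, with 0 higher, 0 lower and 29 within 2-fold. The set shares members with the arginine list above. Among them Aldh18a1, which makes the precursor of proline and ornithine, was 3.81-fold higher, Aldh3a2 2.98-fold and Got2 2.66-fold higher. Nos2 and Arg2 were not among the genes with FPKM used here. The metric in the authors' deposited table implies that Nos2, the inducible nitric oxide synthase, was 7.81-fold higher in the ECM1-sufficient library and Arg2, the mitochondrial arginase, 1.99-fold higher in the ECM1-deficient library, at levels that are unknown.

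Genes of classical activation and of the interferon response lay low among all genes, and those of alternative activation lay within the range of random lists. Of 12 classical genes, 1 was higher, 1 lower and 10 within 2-fold. The list's median of 0.11 was at percentile 0.0300, and relative to the median gene its median was -0.60, with 0 higher and 4 lower. The lower ones were Cxcl10, an interferon-induced chemokine, at 3.94 and 0.417 FPKM, Il18 at 5.49 and 2.56 FPKM, Ccl5 at 1.80 and 0.707 FPKM, and Il1b at 1.81 and 0.805 FPKM. Tnf was at 6.08 and 6.58 FPKM. Cd38 was 2.77-fold higher. Of 22 interferon-stimulated genes, 0 were higher, 3 lower and 19 within 2-fold, with a median of 0.31 at percentile 0.140. Rsad2, the antiviral protein viperin, was 2.81-fold lower, Cmpk2 2.80-fold lower, and Ifit2 was at 9.21 and 0.0514 FPKM. Relative to the median gene the list's median was -0.27, with 0 higher and 6 lower. Ifit1 was at 2.64 and 1.02 FPKM and Isg15 at 7.29 and 5.24 FPKM, whereas Stat2 was at 1.71 and 4.11 FPKM, above the median gene.

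Of 12 genes of alternative activation, the state linked to interleukin-4, 5 were higher, 0 lower and 7 within 2-fold, with a median of 0.80 at percentile 92.2. Besides Arg1 they included Egr2, a transcription factor, 3.59-fold higher, Il4ra, the interleukin-4 receptor chain, 2.97-fold higher, and Retnla, at 0.237 and 1.97 FPKM. None passed 2-fold relative to the median gene. Mrc1, the mannose receptor, was at 7.56 and 14.6 FPKM.

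All 6 measured genes of MHC class II presentation were higher in the ECM1-deficient library. H2-Aa was 3.34-fold, H2-Ab1 2.89-fold, Cd74, the invariant chain, 2.76-fold and H2-DMb1 2.64-fold higher. The median of 1.37 was at percentile 99.99, the highest of the lists with at least 5 measured genes. It was 0.62 relative to the median gene, where all 6 stayed above that gene and 0 passed 2-fold. Cd79a and Cd22 of the B cell list were also at least 2-fold higher in the ECM1-deficient library. They were at 0.378 and 2.43 FPKM and at 2.17 and 5.60 FPKM. The other measured B cell gene, Cd79b, was within 2-fold, at 1.13 and 1.49 FPKM. Itgax of the list for monocytes and small macrophages was at least 2-fold higher too, at 4.93 and 15.6 FPKM. None of these genes passed 2-fold relative to the median gene.

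Of 18 chemokines and receptors, 6 were higher, 0 lower and 12 within 2-fold, with a median of 0.74 at percentile 86.5. After removal of the common shift, 3 were higher, Ccl3, Cxcl13 and Cxcl2, and 2 lower, Ccl4 and Cxcl1. Ccl3 was 4.02-fold and Cxcl13, a B cell attractant, 7.50-fold higher, and Cxcl2 was listed at 0 in the ECM1-sufficient library and at 2.32 FPKM in the other. Ccl4 was at 7.86 and 5.90 FPKM and Cxcl1 at 3.82 and 1.77 FPKM. Of 19 NF-kB and Toll-like receptor genes, 2 were higher, 1 lower and 16 within 2-fold, with a median of 0.72 at percentile 81.9, and relative to the median gene 1 was higher and 1 lower. Tnfaip3, an inhibitor of NF-kB signalling, was 6.67-fold and the kinase gene Ikbke 2.46-fold higher, and Tlr7, a receptor for single-stranded RNA, was 4.20-fold lower. Of 12 genes of GM-CSF receptor and JAK-STAT signalling, 1 was higher, 0 lower and 11 within 2-fold, with a median of 0.66 at percentile 36.4. The higher one was Csf2ra, 2.23-fold, and 0 passed 2-fold relative to the median gene.

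Of 23 genes of cholesterol biosynthesis, 9 were higher, 0 lower and 14 within 2-fold, with a median of 0.89 at percentile 99.3, and 0.23 relative to the median gene, at percentile 99.2. Over genes at 5 FPKM or more, the list was no longer above the middle 95%. The higher genes included Hmgcs1, an early enzyme of the pathway, 2.36-fold higher, Mvd 2.62-fold, Dhcr7 3.27-fold and Stard4, a sterol carrier, 2.86-fold higher. Of 21 genes of lipid uptake, storage and efflux, 6 were higher, 0 lower and 15 within 2-fold, with a median of 0.86 at percentile 99.0. The percentile was 97.4 among length-matched random lists and 96.9 after division by the median ratio, both inside the middle 95%. Abcg1, a cholesterol exporter, was 3.16-fold higher, Pparg 2.49-fold, Scd2 2.36-fold and Apoe 2.09-fold higher. Of 22 genes of glycolysis and hypoxia, 7 were higher, 0 lower and 15 within 2-fold, with a median of 0.92 at percentile 99.6, or 96.4 and inside the middle 95% after that division. Slc2a1, a glucose transporter, was 4.46-fold higher, Eno1 2.60-fold, Pkm 2.57-fold and Gpi1 2.39-fold higher. Of 13 antioxidant genes controlled by NRF2, 3 were higher, 0 lower and 10 within 2-fold, with a median of 0.81 at percentile 88.0, inside the middle 95%. These were Sqstm1 at 2.56-fold, Cat at 2.35-fold and Txnrd1 at 2.11-fold. Relative to the median gene, 0 genes of the cholesterol, lipid and antioxidant lists passed 2-fold in either direction, and among the glycolysis and hypoxia genes 1 was higher, Slc2a1, and 2 were lower, the hypoxia targets Vegfa at -1.09 and Bnip3 at -1.08.

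Of 13 complement genes, 3 were higher, 0 lower and 10 within 2-fold, with a median of 0.88 at percentile 98.2, or 91.7 and inside the middle 95% after division by the median ratio. C5ar1, a receptor for complement fragments, was 3.53-fold, C1qa 3.30-fold and C1qb 2.09-fold higher, and 0 complement genes were higher or lower relative to the median gene. Of 28 genes of the extracellular matrix and its remodelling, 7 were higher, 0 lower and 21 within 2-fold, with a median of 0.69 at percentile 74.5. Mmp27 was 3.40-fold, Plau, the urokinase plasminogen activator, 3.01-fold, Adam8 2.32-fold and Ctsk 2.12-fold higher, and Mmp14 was at 10.3 and 7.68 FPKM. Among the matrix genes 0 were higher and 1, Mmp14, was lower relative to the median gene. Of 15 genes of TGF-beta signalling, 2 were higher, 1 lower and 12 within 2-fold, with a median of 0.58 at percentile 37.2. Tgfb1, the growth factor itself, was 2.82-fold lower, whereas Itgav, an integrin chain that takes part in its activation, was 2.98-fold and Tgfbi 2.56-fold higher. In this list 0 were higher relative to the median gene and 2 lower, Tgfb1 and the receptor gene Tgfbr2, at 6.49 and 4.64 FPKM.

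**Figure D2:**
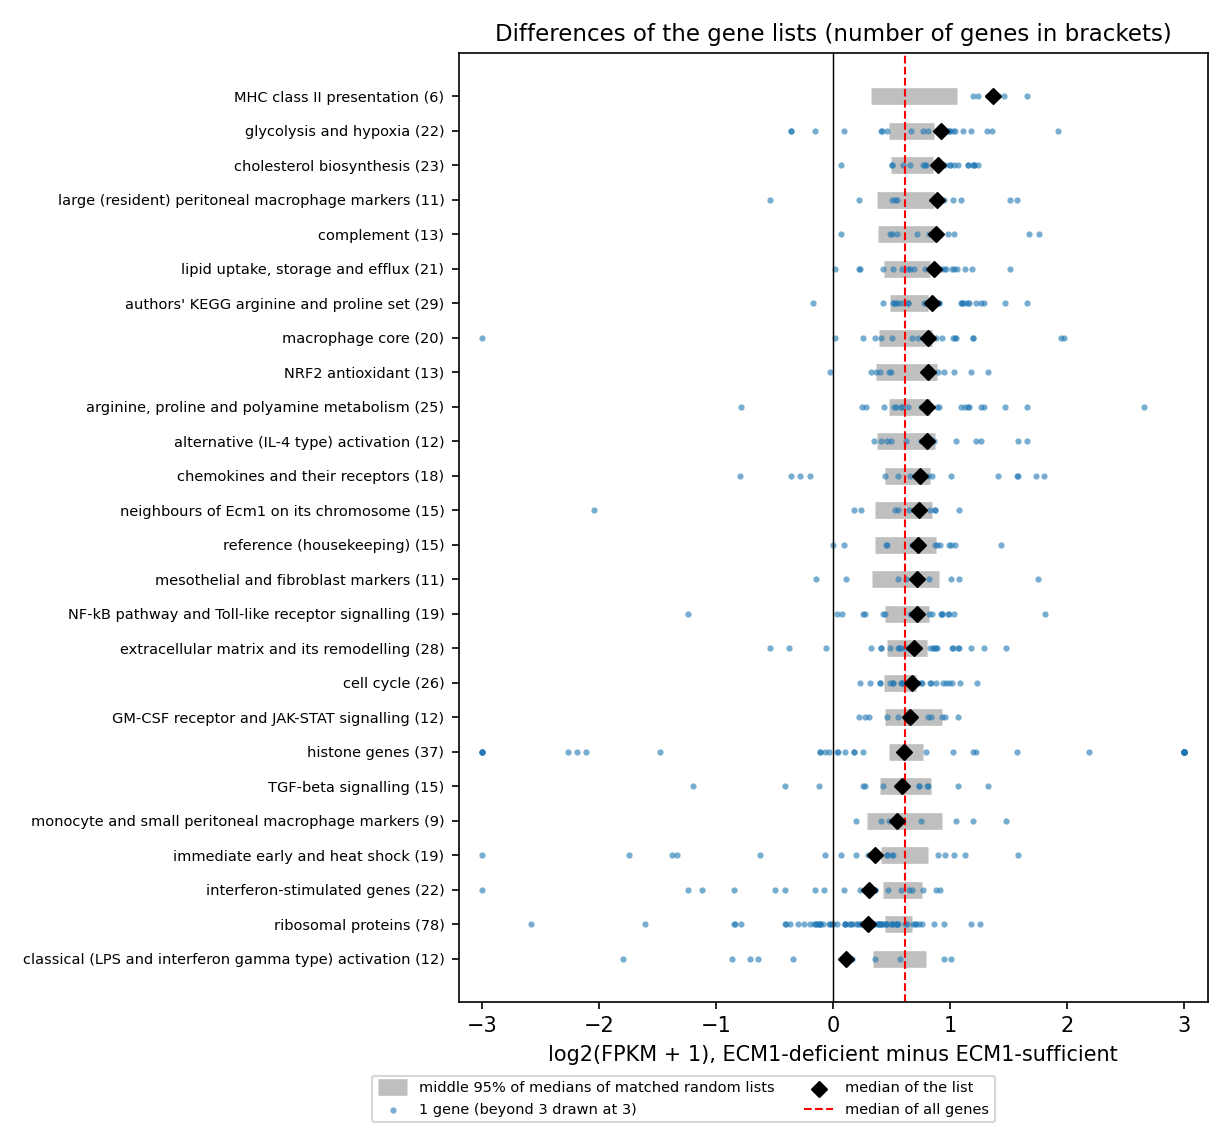
Each row is a gene list with the number of its measured genes. Small points are genes, diamonds the list medians of the difference in log2(FPKM + 1), ECM1-deficient minus ECM1-sufficient, and grey bars the middle 95% of medians of random lists matched on expression. Lists with under 5 measured genes are not drawn. Of those drawn, MHC class II presentation lies farthest right with a median of 1.37, and classical activation farthest left with a median of 0.11.

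Few markers of other cells were measured. The lists of neutrophil, eosinophil and mast cell, B cell, T and NK cell, dendritic cell and erythroid markers held 4, 2, 3, 1, 3 and 1 genes at 1 FPKM or more. Of the 4 neutrophil genes, 1 was higher in the ECM1-deficient library, Csf3r at 2.84-fold, and 3 were within 2-fold. Among these, S100a8 was at 4.98 and 3.69 FPKM. Of the 3 B cell genes, 2 were higher, Cd22 and Cd79a, and 1 was within 2-fold, Cd79b at 1.13 and 1.49 FPKM. No gene of the neutrophil, eosinophil and mast cell, B cell and T and NK cell lists passed 2-fold relative to the median gene, while 1 of the dendritic list and 1 of the erythroid list were lower. In the eosinophil and mast cell list, the tryptase gene Tpsb2 was listed at 0 and 1.31 FPKM, and Siglecf at 1.38 and 1.07 FPKM. Hbb-bs of the erythroid list was at 1.33 and 0.188 FPKM, and Il7r, the T and NK cell entry, at 60.3 and 107 FPKM. Cd24a of the dendritic list was at 34.8 and 1.60 FPKM. Of 11 mesothelial and fibroblast markers, 3 were higher, 0 lower and 8 within 2-fold, with a median of 0.72 at percentile 73.1. Pdgfra was 4.86-fold, Dcn 2.19-fold and Sparc 2.04-fold higher, and relative to the median gene 1 was higher, Pdgfra, and 0 lower. None of the 5 sex-linked genes of the fixed list had FPKM in the table used here.

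Of 11 markers of large, resident peritoneal macrophages, 4 were higher, 0 lower and 7 within 2-fold, with a median of 0.89 at percentile 98.5, or 97.1 and inside the middle 95% after division by the median ratio. Cxcl13, Saa3, F10 and Thbs1 were the higher ones, Saa3 at 2.93-fold, F10 at 2.18-fold and Thbs1 at 2.35-fold. With the common shift removed 1 was higher, Cxcl13, and 1 lower, Serpinb2, at 7.69 and 4.96 FPKM. Gata6, which controls the resident state, was at 2.15 and 3.46 FPKM. Of 9 markers of monocytes and small peritoneal macrophages, 3 were higher, 0 lower and 6 within 2-fold, with a median of 0.55 at percentile 26.9. Itgax was 3.15-fold, F13a1 2.66-fold and Chil3 2.29-fold higher, and 0 passed 2-fold relative to the median gene.

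Of 26 cell cycle genes, 3 were higher, 0 lower and 23 within 2-fold, with a median of 0.67 at percentile 93.1, or 97.85 and above the middle 95% after division by the median ratio. Plk1 was 4.71-fold, Ccnb2 3.18-fold and Top2a 3.04-fold higher, from 0.572, 0.883 and 1.23 FPKM, and 0 of the 26 passed 2-fold relative to the median gene. Of 78 ribosomal protein genes, 2 were higher, 2 lower and 74 within 2-fold. The median of 0.29 lay below those of all 10000 random lists, and relative to the median gene 0 were higher and 10 lower. Rpl35 was 2.39-fold and Rpl4 2.26-fold higher, and Rpl39 was 6.06-fold and Rpl29 3.16-fold lower. Of 15 reference genes, 3 were higher, 0 lower and 12 within 2-fold, with a median of 0.73 at percentile 76.7. Gusb was 2.08-fold and Sdha 2.06-fold higher, while Actb was at 501 and 535 FPKM, and 0 passed 2-fold relative to the median gene.

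Of 19 immediate early and heat shock genes, 3 were higher, 4 lower and 12 within 2-fold, with a median of 0.36 at percentile 1.02. The counts relative to the median gene were 0 higher and 5 lower. Jund and Ier2, both with 1 exon, were listed at 0 in the ECM1-deficient library, against 11.4 and 2.35 FPKM in the other. Btg2, which restrains cell growth, was 4.31-fold lower. The transcription factor gene Klf6 was at 42.9 and 16.4 FPKM, and Ier3 at 10.4 and 6.38 FPKM. Over genes with 3 or more exons the list's median was 0.48 and at percentile 15, and at 5 FPKM or more it was at percentile 42.3, both inside the middle 95% of random lists.

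The 24 genes with the largest differences were mostly genes with 1 exon. The 12 highest in the ECM1-deficient library were mt-Cytb, the adaptor gene Ywhah and the 10 histone genes Hist1h4b, Hist1h2ab, Hist1h2ap, Hist1h1e, Hist1h3e, Hist1h2bb, Hist1h2ad, Hist1h3a, Hist1h2ac and Hist1h2ag. All but Ywhah were listed at 0 in the ECM1-sufficient library. The 12 lowest were mt-Co1, Rps12-ps3, Lyz2, Hist1h4d, Rpl27-ps3, Eid1, Imp3, Hist1h3d, Hist3h2a, Hist2h2bb, Itpripl2 and Cd24a, and all but Lyz2 and Cd24a were listed at 0 in the ECM1-deficient library. The mitochondrial gene mt-Co1, a subunit of cytochrome c oxidase that every macrophage uses, was at 1299 FPKM in the ECM1-sufficient library and at 0 in the other, and mt-Cytb was at 0 and 209 FPKM. Of the 13 mitochondrially encoded genes in the fixed list, only 3 had FPKM used here. Of these 3, 1 was higher, 1 lower and 1 within 2-fold, also relative to the median gene. Of 37 histone genes, 16 were higher, 8 lower and 13 within 2-fold, with a median of 0.60 at percentile 41.8, and relative to the median gene 14 were higher and 8 lower. Without members near 0 in 1 library the median was 0.14, below the middle 95%. Ywhah, with 2 exons, was at 0.115 and 103 FPKM.

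Among 2718 genes with 3 or more exons and 5 FPKM or more in both libraries, a ranking chosen after their values were seen, 28 were higher and 143 lower at least 2-fold relative to the median gene. The highest was Rnf7, a ubiquitin ligase subunit, 12.1-fold higher as deposited, followed by Arl6ip5 at 7.54-fold and S100a10 at 6.60-fold. Arpc4 was 5.72-fold and Pfn1, which encodes the actin-binding protein profilin, 5.53-fold higher. Atpif1, Spag7, Atp6v0e, Snx12, Atp6v0d2, Actg1 and Csrp1 completed the 12. After Lyz2, the lowest were Cox7a2l, a factor of respiratory complexes, 10.8-fold lower, Erh 7.73-fold, Rpl39 6.06-fold and Tsc22d3, a glucocorticoid-induced gene, 5.37-fold lower. Gpx1, a peroxide-removing enzyme, was at 225 and 44.97 FPKM. Mrps21, Ykt6, Atp1b3, Morf4l2, Arf3 and Ctsz completed that list, with Ctsz, the lysosomal protease cathepsin Z, at 1078 and 356 FPKM.

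The authors' deposited table of gene ontology listed 2592 biological process terms for 4944 genes against 23313. The 4183 genes it named that also had FPKM here were all at least 1.5-fold higher in the ECM1-deficient library, and 0 lower genes entered it. In the authors' deposited table, response to endoplasmic reticulum stress held 109 of 196 genes, a fold enrichment of 2.62, innate immune response 165 of 494, at 1.57, phagocytosis 64 of 142, at 2.13, and cholesterol biosynthetic process 26 of 43, at 2.85. Antigen presentation of peptide antigen through MHC class II held 15 of 19, at 3.72, and vacuolar acidification 8 of 12, at 3.14. These terms were chosen from that table after its values were seen, and 2136 of the 2592 terms had a false discovery rate under 5% there. Of the 10403 genes listed here, 4943 were at least 1.5-fold higher and 368 lower. The shares within terms are not comparable with these, since the terms count against 23313 genes. The same background raises the fold enrichment of any term made mostly of genes expressed here.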

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

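The added settings, genes with 3 or more exons, random lists matched on length and lists without members near 0 in 1 library, were chosen after the data were seen. The main counts at 2-fold were 1337 higher and 196 lower. Dividing by the median ratio gave 221 and 431, and equal sums of FPKM gave 833 and 387. Both remove all or part of the common shift, which by construction moves genes from higher towards lower. It does not fix how many lie past 2-fold on either side, such as the excess of lower genes after the median division. Thresholds gave 4849 and 332 at 1.5-fold and 109 and 72 at 4-fold. A pseudocount of 5 gave 286 and 89, by shrinking low genes, and a pseudocount of 0.1 gave 2944 higher genes, with 262 lower. The minimum of 5 FPKM gave 122 lower genes and 3 or more exons 104, both with fewer genes tested, while the higher genes were 1004 and 1245. No FPKM minimum and the highest row per symbol left both counts at the main values. After division by the median ratio, the histone median, which had been inside the middle 95%, went from 0.60 to -0.097. Of the low lists, 4 changed sign after that division, again by construction. These were classical activation, to -0.60, interferon-stimulated genes, to -0.27, immediate early and heat shock genes, to -0.22, and ribosomal proteins, to -0.49. With equal sums, 3 low lists changed sign for the same reason, at -0.33 for classical activation, -0.013 for interferon-stimulated genes and -0.16 for ribosomal proteins. At 5 FPKM or more the interferon-stimulated median was -0.027, for which the cause was not tested. Of 26 lists, 7 lay above and 4 below the middle 95% of random lists. These were 4 and 4 with division by the median ratio, 3 and 4 with equal sums and with a pseudocount of 0.1, where only MHC class II, cholesterol and the KEGG set stayed above, 5 and 4 with length-matched random lists, where the lipid genes at 97.4 and the KEGG set at 96.9 were inside, and 7 and 4 with the highest row. Without members near 0 they were also 7 and 4, but histone genes were below and immediate early and heat shock genes inside. Among 25 lists they were 3 and 2 at 5 FPKM or more, with MHC class II, lipid and glycolysis genes above, and 7 and 3 with 3 or more exons. Complement went to percentile 91.7, glycolysis to 96.4, lipid genes to 96.9 and resident macrophage markers to 97.1 after division by the median ratio, inside the middle range, while cell cycle genes went above it, to 97.85. MHC class II lay above the range, and classical activation, where its percentile could be had, interferon-stimulated and ribosomal genes lay below it, under each of these alternatives. Among the 139 named genes, 94 moved by over 1.5-fold under the median division, 39 with equal sums, 38 with a pseudocount of 0.1 and 0 with the highest row. Depth is unknown, so no counting error can be attached to low FPKM.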

Other observations

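All tests below were chosen after the patterns they bear on had been seen. For Lyz1 and for length-matched lists, the prediction was written before the result of its own test. For the common shift, single-exon genes, cell division, macrophage content and a failed estimate, it was written after. Against random lists matched on expression and transcript length, the higher of the percentiles of interferon-stimulated and classical activation genes was 0.1, and ribosomal protein genes lay at percentile 0.01.

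The authors' KEGG arginine and proline set was scored again over the genes listed here, with the 32 of its 34 members that had FPKM, Nos2 and Arg2 being left out. Nos2 had a metric of 3.86 in the authors' deposited table, the ECM1-sufficient direction, so leaving it out favours a negative score. Arg2 had a metric of -1.66, the ECM1-deficient direction. The authors' ranking also reached at least 10660 genes, so these scores are not those of the authors' table. Its enrichment score was -0.444 with FPKM as deposited and -0.506 after division by the median ratio, and 1 and 7 of 1000 random sets matched on expression reached a score as low. Of these random sets, which were not matched on transcript length, 88.4% had a negative score as deposited and 42.7% after the division. A negative sign, the ECM1-deficient direction, was thus the rule for random sets from the FPKM as deposited, but not after the division.

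Most genes were higher in the ECM1-deficient library, with a median ratio of 0.79 on the log2 scale. If a few abundant listed genes of usual length held the difference, the FPKM sums would be about equal. Their log2 ratio was 0.45, less than the median ratio. The sums were not weighted by transcript length, so they cannot decide how much such genes contribute. A trend with transcript length leaves the shift in place, since the lowest of 10 equal groups by length, the shortest transcripts, still had a median of 0.49. RNA that is not in the table, such as non-coding transcripts, may take a larger share of the ECM1-sufficient library. This was not tested, as 0 of the listed genes are non-coding and the FPKM sums were not weighted by transcript length. FPKM are relative to the mapped fragments, so a larger RNA content per cell in the ECM1-deficient sample would not by itself raise them. RNA content was not tested.

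Of genes at 5 FPKM or more in 1 library, 67 were under 5% of that in the other, 30 of them higher and 37 lower in the ECM1-deficient library. Single-exon genes made up 62.7% of them, 42 genes, against 2.36% of the 4492 genes at that level, so a different estimate of unspliced genes in the 2 libraries is a candidate explanation for most. If histone FPKM followed cell division in these libraries of polyadenylated RNA, which was not tested, a difference would move histone genes one way. Of 18 past 4-fold relative to the median gene, 11 were higher and 7 lower, 38.9% against the majority. Many histone genes are themselves among the single-exon genes of the 67, so their directions cannot decide about cell division. The cell cycle list was not used for this question. The spread of differences also fell with exon number, from an SD over genes of 2.501 at 1 exon to 0.34 at 10 or more. Ifit2, Ywhah and Pole3 are spliced genes of the 67 and are not covered by that explanation.

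Lyz2 was nearly lost from the ECM1-deficient library. Fewer macrophages would lower the other core genes too, but the median of these 19 was 0.053 relative to the median gene. Reads moved to the paralog Lyz1 would need a large excess there, and Lyz1, at 20.2 and 37.0 FPKM, made up 0.608% of what Lyz2 lacked. A failed abundance estimate may be the cause, since 2 of the other spliced genes of 100 FPKM or more, Gm10116 and Ywhah, were also under 5% in one library, among 297 such genes, and this is too few to decide. A disrupted Lyz2 locus in the ECM1-deficient mice, as with some macrophage Cre drivers, would lower Lyz2 as well, but the labels name no such allele and it was not tested.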
